A study of Ptychidio jordani with 7 samples.

How the data were processed

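RNA was sequenced from 7 tissues of the ratmouth barbel, with 1 sample per tissue: heart, muscle, liver, kidney, spleen, gill and fin. Per the labels, total RNA was extracted with TRIzol and libraries were made with a Vazyme VAHTS kit for an MGI sequencer. The submitters' notes name HISAT2 2.2.1 and RSEM 1.3.3. The genome build and the annotation are not given in the sources used here. The authors deposited 1 table of FPKM for 26107 genes, printed to 2 decimals with a lowest positive value of 0.01. Of these genes 21296 had a symbol, 22993 a symbol or a description and 3114 neither, and 2467 were loci outside the named annotation. The deposited FPKM carry no read totals, so depth and counting error are unknown and no interval is given.

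The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A gene was counted as detected at an FPKM of at least 1. Pearson correlations between libraries used log2(FPKM + 1) of the 21151 genes with an FPKM of at least 1 in some tissue, with average-linkage clustering on 1 minus the correlation. A tissue-enriched gene had an FPKM of at least 10 in a tissue and an FPKM + 1 of at least 5 times the highest of the other 6. The specificity index tau was computed on log2(FPKM + 1), with 0.85 and 0.3 as limits. Muscle was compared with heart, spleen with kidney and fin with gill by the same 5-fold rule, for genes with an FPKM of at least 10 in the higher of the pair.

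Before the data were examined, 27 gene lists were fixed, together with the rules, the alternatives and the choice of named genes. Each list was scored in each tissue by the median over its genes of log2(FPKM + 1) minus the mean of the other 6, and by its percentile among 10000 random lists matched on expression in 20 bins. A list was called above percentile 97.5 or below the mirror limit. The lists covered fast, slow and cardiac muscle, hepatocytes, complement, liver enzymes, kidney tubule, granulocytes, erythroid, B, T and NK cells, macrophages, spleen stroma, thrombocytes, gill ionocytes, neuroepithelial and mucous cells, epidermis, bone and dermis, pigment cells, nerve, ribosomal proteins, oxidative phosphorylation, glycolysis, fatty acid oxidation, cell division, exocrine pancreas and gut. After the data were seen, 4 lists were added: egg coat, oocyte, globin and red cell, and Hox genes of the tail. Named genes were the 5 tissue-enriched genes of largest ratio and the 3 most abundant in each tissue, 4 per list in its tissue and 5 per side of each pair. Genes with no name were left out of the naming only. Some genes that this rule selects are not reported here.

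Alternatives were another pseudocount, other limits on FPKM and fold, rescaling to a common sum, median-of-ratios scaling over 17448 genes, Spearman correlation, another reference for the lists, 1 gene per root, and leaving out tissues. Leaving out genes on the egg coat profile, or kidney and the library labelled spleen together, was chosen after seeing the data. So was leaving a library out of the reference of a list, or the library labelled spleen out of tau. Leaving out single tissues from the enriched counts was planned. With 1 sample per tissue no test between groups was run. The rules were tested on simulated libraries made from the mean of each gene over the 7 libraries, with small random noise. In the simulated gill library 50 genes per fold were raised. With so little noise and no other difference between tissues, calls among unchanged genes could hardly occur. The enriched rule called 0 of 50 genes at 2-fold and 4-fold and 50 of 50 at 8-fold and 16-fold, and no unchanged gene. The fin against gill rule called 0, 3, 50 and 50, and the list rule 10 of 10 changed lists at each fold and 2 of 200 unchanged ones. List calls were counted at the upper limit only. Each changed list held 30 genes drawn from the same 50 raised ones, so these lists overlapped.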

Results

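Gene expression was measured by RNA sequencing in 7 tissues of the ratmouth barbel (Ptychidio jordani), a freshwater fish of the carp family: heart, muscle, kidney, gill, liver, spleen and caudal fin. The libraries accompany an assembly of this species' genome at chromosome scale, and the design implies a comparison of the tissues with each other. Each tissue was represented by 1 sample, so no difference below has a replicate check and no p-value is given. The deposited table lists 26107 genes with a value in fragments per kilobase scaled to the mapped fragments of the library (FPKM) for each library. The table gives no read totals, so the depth of the libraries is unknown, and genomic positions are not used here. An FPKM is a share of a library, so a few very abundant genes lower the values of all others. The factors that would bring the libraries to 1 common median ran from -1.89 in liver and -1.13 in the library labelled spleen to 1.05 in kidney on the log2 scale. They were -0.35 in heart, 0.63 in gill, 0.65 in muscle and 0.76 in fin. The percentiles given for gene lists compare each list with random lists in the same library, and for lists in the tissues they were chosen for, those that crossed a limit after median-of-ratios scaling are given with both values.

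The sample called spleen is written as the library labelled spleen throughout, because its leading genes were those of the liver library and the lists of erythroid, T and NK cell, macrophage and thrombocyte genes were low in it. Values below are FPKM, and a fold or log2 ratio is on the FPKM + 1 scale unless stated otherwise. Ratios of gene lists between libraries in the closing section are of FPKM without a pseudocount. A gene was called tissue-enriched at an FPKM of at least 10 in a library and at least 5 times the highest of the other 6. Where several genes of the table carry 1 name, the copy quoted is the highest in the library described, among those that met the rule in use. Another copy of that name can be higher in another library. Identifiers are given for genes of the named annotation. Values of such genes are uncertain, since the estimation can divide reads between near-identical copies. No fold is given against an exact 0, which is reported as listed at 0.

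Globin, vitellogenin, contractile, egg coat and keratin genes were each among the 3 most abundant named genes of at least 1 library. The hemoglobin genes hba (Pjo03032) and hbb (Pjo03031) led the kidney library at 67752 and 59808, followed by hbb2 (Pjo03028) at 5492, and the heart library at 31174 and 24914. The third named gene of heart was MYL4 (Pjo05118), an atrial myosin light chain, at 11018. The liver library was headed by vtg1 (Pjo21814), the yolk precursor vitellogenin, at 47063, apolipoprotein A-I (Pjo14864) at 38007 and APOC1 (Pjo16447) at 21559. The same 3 genes headed the library labelled spleen among named genes, with apolipoprotein A-I at 40675, vtg1 at 30655 and APOC1 at 24903. In muscle the most abundant named genes were a ladderlectin-like gene (Pjo09485) at 12938 and the egg coat genes ZP3 at 9431 and ZP4 (Pjo20597) at 7937. GSTP1 (Pjo14629), a glutathione transferase, led the gill library at 11454, followed by hba at 8918 and hbb at 8292. An ictacalcin-like gene (Pjo16466) led the fin library at 16711, with the epithelial keratin krt8 (Pjo23181) at 14981 and a lipocalin-like gene (Pjo23951) at 11270.

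Genes with an FPKM of at least 1 numbered 8816 in liver, 11009 in the library labelled spleen, 12643 in heart, 14514 in muscle, 16010 in kidney, 16201 in gill and 16811 in fin. The 10 highest genes held 36.3% of the summed FPKM in liver, 33.3% in the library labelled spleen, 21.9% in kidney and 19.6% in heart. In fin, muscle and gill they held 13.02%, 11.6% and 11.0%. Without globin genes the share in kidney was 7.27% and that in heart 14.4%. With a minimum of 5 the count in liver was 3425 and that in the library labelled spleen 4690, and with a minimum of 0.1 they were 15978 and 17555.

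**Figure D1:**
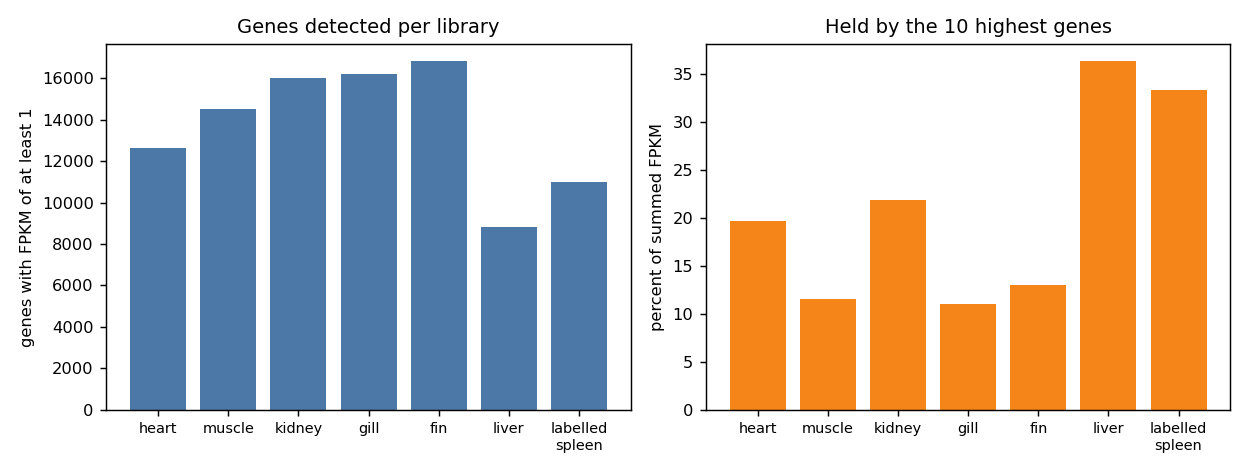
Bars show, for each of the 7 libraries (1 sample each), the number of genes with an FPKM of at least 1 (left) and the percent of the summed FPKM held by its 10 highest genes (right). Liver has the fewest genes, 8816, and the highest share, 36.3%.

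The closest pair of libraries was liver and the library labelled spleen, with a Pearson correlation of 0.960 across 21151 genes on the log2 scale. Muscle and kidney followed at 0.885, and gill and fin at 0.783. Both striated muscles were less alike: heart and muscle correlated at 0.597, and at 0.640 without the genes that followed the egg coat profile, a set chosen after the data were seen. Kidney and the library labelled spleen correlated at 0.636. The lowest value was that of muscle and gill, 0.413. Average-linkage clustering joined these 3 closest pairs first. The correlations run across genes, which are not independent replicates.

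**Figure D2:**
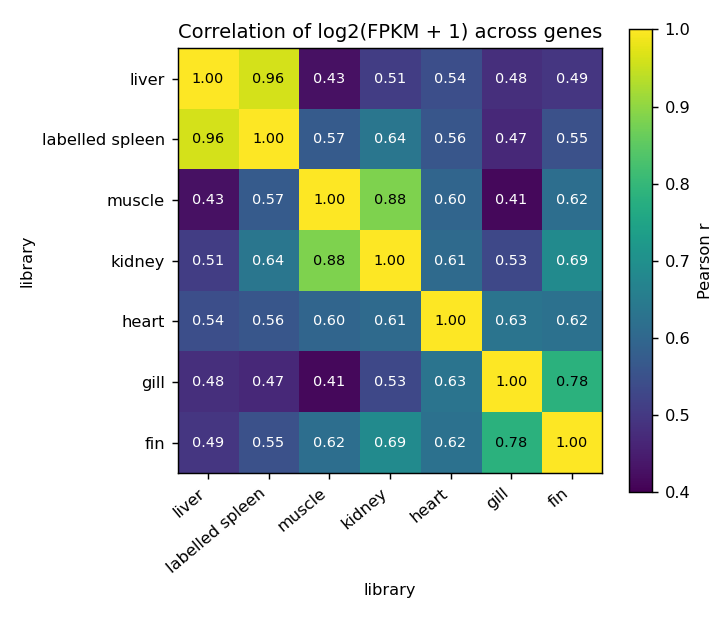
Each cell is the Pearson correlation of log2(FPKM + 1) across 21151 genes between a pair of libraries (1 sample each), on a colour scale from 0.4 to 1. The pair of liver and the library labelled spleen is at 0.960 and that of muscle and kidney at 0.885.

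Heart carried 329 tissue-enriched genes, which together held 26.2% of its summed FPKM. Among named genes, the largest ratios over the next library belonged to the sarcomere genes MYH7 (Pjo01657, a slow and cardiac myosin heavy chain), MYL4 and TNNC1 (Pjo23378, troponin C) and to the natriuretic peptide genes nppa (Pjo08642) and nppb (Pjo08643). MYH7 was 5515 in heart and at most 0.2 elsewhere, a log2 ratio of 12.17, and TNNC1 was 4063 in heart and 0.28 in gill. nppa was 3521 in heart, and nppb was 3164 in heart and listed at 0 in all other libraries. Of 42 genes in the cardiac muscle list, 30 were highest in heart and 18 were enriched there. The list's median was 3.15 log2 units above the mean of the other libraries, at percentile 100 of 10000 random lists. Its leading members besides MYL4 and nppa were MYL7 (Pjo08842), at 4024, and the cardiac actin ACTC1 (Pjo19910), at 3277 in heart and 7.78 in gill. Another ACTC1 copy (Pjo24801) was 1108 in muscle and 0.82 in heart. Genes of energy metabolism were also high in heart. Of 58 oxidative phosphorylation genes, 43 were highest there, with a median difference of 1.71 at percentile 100, and ATP5F1B (Pjo12006) was 1666 in heart against 589 in muscle. Cox7a2 (Pjo15231), Uqcrq (Pjo14374) and COX7B (Pjo20787) were 3320, 2392 and 1539. Of 27 glycolysis genes, 14 were highest in heart, where the list's median was 247 against 72.9 in muscle. The fatty acid oxidation list was 0.77 higher in heart, at percentile 99.89, with Acadm (Pjo01704), ETFB (Pjo15905), HADHB (Pjo20488) and CPT1A (Pjo18048) at 300.0, 217, 210.1 and 164. Against the highest of the other libraries, the fatty acid oxidation median turned to -0.34. A 10-fold rule gave 178 enriched genes in heart.

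Muscle carried 85 tissue-enriched genes, led among named genes by fast-fibre sarcomere genes. These were TNNI2 (Pjo24475, fast troponin I) at 4619, the myosin heavy chains MYH1B at 1863 and MYH13 (Pjo05530) at 1236, MYLPF (fast myosin light chain) at 4226 and TNNT3 (Pjo07736, fast troponin T) at 3438. The highest other value was in gill for each, between 0.17 for MYH13 and 3.15 for MYLPF. In the fast skeletal muscle list 34 of 42 genes were highest in muscle and 16 were enriched, with a median difference of 4.0 at percentile 100. Its most abundant member, the creatine kinase CKM (Pjo05440), was 7155 in muscle and 5885 in heart, and skeletal actin acta1 (Pjo16962) was 6707 in muscle and 0.56 in heart. The slow skeletal muscle list was split between striated muscles: 11 of 27 genes were highest in muscle and 11 in heart. MYL2 (Pjo10851), Tnnc1 (Pjo23056) and Tnni1 (Pjo24663) were 1291, 221 and 204 in muscle and 0.8, 18.7 and 0.4 in heart, while the myoglobin gene mb (Pjo00192) was 236 in muscle and 10491 in heart. Another Tnni1 copy (Pjo07115) was 2839 in heart and 0.08 in muscle. The slow muscle list's median in muscle, 0.72 at percentile 97.96, turned to -0.11 with 1 gene per gene root and to -0.55 against the highest of the other libraries. Its percentile was 97.04 without the library labelled spleen and 92.85 without kidney. The glycolysis list was at 1.25 and percentile 94.74 and the oxidative phosphorylation list at 0.66 and percentile 81.04, neither above the limit of 97.5. Glycolysis members in muscle were gapdh (Pjo16701) at 3175, the muscle form PGAM2 (Pjo21208) at 539, ENO3 (Pjo22508) at 458 and ENO1 (Pjo23002) at 254. The oxidative phosphorylation genes Uqcrq, COX7B and ndufa4 were 779, 656 and 653.

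Egg genes were also abundant in the muscle library, in 2 lists that were added after the data were seen. The 41 egg coat genes held 10.8% of the summed FPKM of muscle and 5.6% of that of kidney, with medians of 676 and 429. Their medians were 75.3 in fin, 37.0 in the library labelled spleen, 18.9 in heart, 5.04 in liver and 0.57 in gill. The 1011 genes that followed the egg coat profile held 31.8% of the summed FPKM of muscle and 17.3% of that of kidney. They held 3.65% in fin and 1.87% in the library labelled spleen. These genes were selected after the data were seen by their ratios between libraries, not by function. ZP2 (Pjo20421) was 592 in muscle and 314 in kidney. In the oocyte list 21 of 28 genes were highest in muscle. Its members zar1 (Pjo10830), wee2 (Pjo18237), BMP15 (Pjo07570) and LHX8 (Pjo01485) were 1137, 223, 184 and 142 in muscle and 612, 174, 131 and 93.4 in kidney. Without the kidney library the muscle count was 1142 in place of 85, and without heart it was 172.

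Kidney carried 70 tissue-enriched genes. Among those of largest ratio, Slc6a13 (Pjo18630, a carrier of GABA and taurine), slc22a6 (Pjo20977, an organic anion transporter), PDZK1 (Pjo09820, a scaffold of brush border transporters) and GUCA2A (Pjo11745, guanylin) were 278, 116, 104 and 61.1 in kidney. Muscle was next for all of them, at 8.7, 3.28, 3.5 and 1.71. NDUFB1 (Pjo20521), a respiratory chain subunit and first by ratio among named genes, was 64.9 in kidney and listed at 0 in every other library. Of 46 genes in the kidney tubule and glomerulus list, 27 were highest in kidney and 8 enriched, with a median difference of 1.66 at percentile 100. The phosphate carrier slc20a1a (Pjo08950) was 104 and CDH17 (Pjo16358), a cadherin of kidney tubules, 49.6. Blood genes were high as well. In the erythroid list 13 of 22 genes were highest in kidney, with a median difference of 2.33 at percentile 100, and alas2 (Pjo09163, heme synthesis) and slc4a1 (Pjo03587, the red cell anion exchanger) were 482 and 274. The heart library was close behind, at a median of 24.8 against 25.1. In the granulocyte and blood progenitor list 17 of 31 genes were highest in kidney, among them the lysozyme gene LYZ (Pjo23827) at 1573 and MMP9 (Pjo09090) at 211, with CEBPA (Pjo07781) at 155 and MMP13 (Pjo10741) at 104. Its median difference of 0.86 lay at percentile 88.7, under the limit, and at percentile 99.02 after median-of-ratios scaling. The B cell list was 0.70 higher in kidney, at percentile 99.77, with 13 of 37 genes highest there, and 0.93 higher in gill, at percentile 99.94, with 16. CD22 (Pjo15997) was 49.7 in kidney and 6.21 in heart, and BLNK (Pjo13972) was 9.51 in kidney and 5.42 in gill. CD74 (Pjo20897) was 263 in kidney and 1926 in gill, and pax5 (Pjo00810) 11.9 in kidney and 11.2 in muscle, where the egg coat list was also high. Against the highest of the other libraries the B cell median in kidney was -0.17. The thrombocyte list did not stand apart in kidney, at 0.10 and percentile 5.67. Its members Gp1bb (Pjo09447), Gp9 (Pjo23371), fli1 (Pjo16055) and F13a1 (Pjo08370) were 122, 46.6, 28.3 and 10.3 there. The cell division list was 3.20 higher in kidney and 3.51 higher in muscle, both at percentile 100. 26 of its 33 genes were highest in muscle. ccnb1 (Pjo04975), ube2c (Pjo07125), rrm2 (Pjo20165) and ccnb2 (Pjo07891) were 712, 425, 338 and 325 in kidney and 1191, 772, 729 and 477 in muscle, the same libraries in which the egg coat list was high. Against the highest of the other libraries the median in kidney was -0.36. The 14 genes of the globin and red cell list, added after the data were seen, held 18.0% of the summed FPKM of kidney and 8.80% of that of heart. Without muscle the kidney count of enriched genes was 642, without gill 109, after median-of-ratios scaling 32 and with a 10-fold rule 34.

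Muscle and kidney shared 539 genes that were at least 10 in both and at least 5 times any other library. Gill and fin shared 358 such genes, liver and the library labelled spleen 350, and heart and muscle 79.

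**Figure D3:**
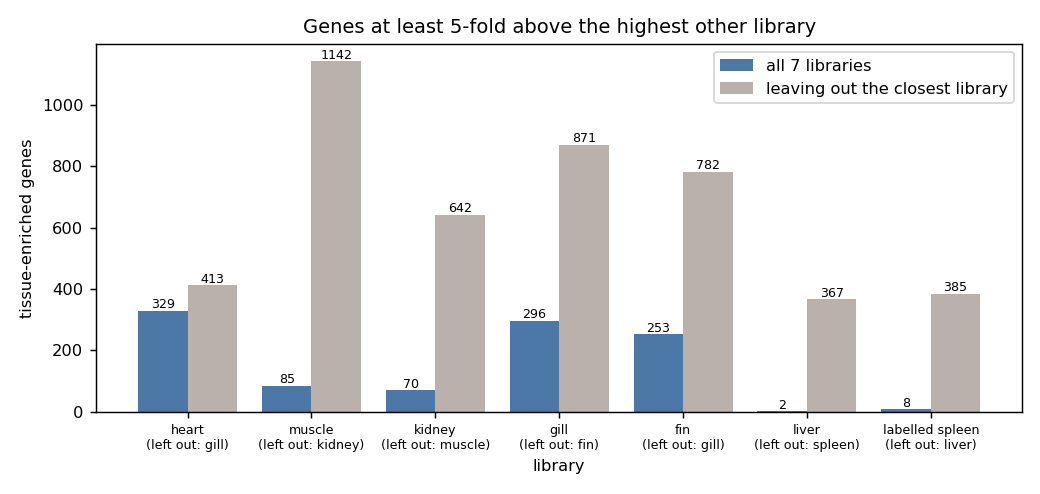
Bars show the number of tissue-enriched genes in each library (1 sample each) against all 6 others and after leaving out the closest library, named under each bar. Liver goes from 2 to 367 and muscle from 85 to 1142.

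Gill carried 296 tissue-enriched genes. The largest ratios among named genes were those of cnfn-b (Pjo08107, a cornifelin) at 1283, TSTD1 (Pjo23893, a sulfur transferase) at 901, the mesothelin-like gene Mslnl (Pjo03074) at 249, the ammonia channel gene rhcg1 (Pjo08292) at 392 and rergl (Pjo16321) at 1042. The next highest library was at or below 4.61 for each. In the list of gill ionocytes and acid-base transport 18 of 33 genes were highest in gill and 10 enriched, with a median difference of 1.07 at percentile 100. The ammonia transporter gene rhbg (Pjo16308) was 418 in gill and 12.1 in fin, the sodium/proton exchanger SLC9A3 (Pjo19012) 386 and 5.51 in fin, and the carbonic anhydrase ca2 (Pjo23675) 294 and 15.9 in kidney. The list of neuroepithelial, mucous and vascular cells had 13 of 23 genes highest in gill and a median difference of 0.68 at percentile 99.31. agr2 (Pjo19390) was 215, the endothelial genes PECAM1 (Pjo06574) and CDH5 (Pjo07669) 61.7 and 27.6, and the mucin Muc2 44.3. CDH5 was slightly higher in heart, at 28.3. T and NK cell genes were higher in gill than in 5 of the 6 others. Of 35 genes 24 were highest in gill, with a median difference of 1.27 at percentile 100, and the list median was 2.43 in gill and 3.42 in fin. gata3 (Pjo04269), Ccr9 (Pjo01830), CD3E (Pjo15788) and LCK (Pjo19801) were 405, 395, 28.2 and 25.1 in gill. In fin they were 8.37, 313, 15.8 and 4.75. Leaving out fin raised the gill count to 871, and a 10-fold rule lowered it to 153.

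Fin carried 253 tissue-enriched genes. KRT19 (Pjo00043), an epithelial keratin, was 1465 in fin and 0.11 in gill, Prg4 (Pjo01575, lubricin) 1615 and 0.98 in kidney, and FGFBP2 (Pjo14462) 917 and 0.58 in gill. A gene named for the gamma subunit of thread biopolymer filaments (Pjo01829) was 189.8 and ALOX5 (Pjo04074), a lipoxygenase, 145. In the epidermis list 23 of 34 genes were highest in fin and 7 in gill, with median differences of 4.36 and 2.61, both at percentile 100. Krt17 (Pjo22082) was 5598 in fin and 2481 in gill, Itgb4 (Pjo09329, a hemidesmosome integrin) 586 and 53.3, ANXA1 (Pjo05700) 2098 and 2046, Epcam (Pjo13285) 2940 and 4472, and cldn7b (Pjo11046) 289 and 489. Against the highest other library the epidermis median in gill was -0.82. In the list of bone, dermis and fin ray 26 of 40 genes were highest in fin and 13 enriched, with a median difference of 2.52 at percentile 100. The matrix genes LUM (Pjo04404), SPARC (Pjo14147), COL1A1 (Pjo13087) and col1a2 were 527, 469, 380 and 342 in fin, and at most 8.73, 104, 32.2 and 31.9 elsewhere. The pigment cell list did not pass the limit in fin, at 0.39 and percentile 95.66. FHL2 (Pjo09828), PMEL (Pjo11469), GART (Pjo01119) and SOX10 (Pjo02648) were 11.3, 9.39, 7.9 and 5.62 there. With a pseudocount of 0.1 the list lay at percentile 99.48. The nerve and glia list was at 0.02 and percentile 34.86, although the myelin gene MBP (Pjo16811) was 102 in fin and at most 35.9 elsewhere. Pmp22 (Pjo12391) was 151 in fin and 148 in gill, and S100B (Pjo22049) was 11.0 in fin. Against the highest of the other libraries the nerve and glia median was -0.07. Leaving out gill raised the fin count to 782, a 10-fold rule lowered it to 123, and median-of-ratios scaling gave 165.

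Liver carried 2 tissue-enriched genes and the library labelled spleen 8. The only named one in liver was tc1a, a transposase gene, at 12.9 and listed at 0 elsewhere. The only named one in the library labelled spleen was a multidrug resistance-associated protein 1-like gene, at 76.2 against 4.07 in kidney. Without each other, the same libraries carried 367 and 385. The liver count was 5 without gill and 21 after median-of-ratios scaling, and that of the library labelled spleen 13 after this scaling. In the 350 genes enriched in both, the median log2 ratio of liver over the library labelled spleen, without a pseudocount, was -0.17. Of 49 hepatocyte genes, 43 had an FPKM of at least 1 in both libraries. 5 were highest in liver and 36 in the library labelled spleen, with medians of 279 and 291 and median differences of 5.82 and 6.04, both at percentile 100. The fibrinogen genes FGB (Pjo00985) and fgg (Pjo00761) were 10018 and 6308 in liver and 11947 and 7828 in the library labelled spleen, and at most 0.42 and 0.24 elsewhere. The transferrin gene tf (Pjo01531) and the liver fatty acid binding protein gene fabp10a (Pjo15882) were 8409 and 7228 in liver and 10201 and 11909 in the library labelled spleen. Complement genes had median differences of 4.57 and 4.87, with c3 (Pjo00161) at 1325 and 1402, CFI (Pjo22535) at 1333 and 1497, C7 (Pjo21168) at 846 and 937, and Cfb (Pjo20987) at 515 and 646. The enzymes of bile acid, cholesterol and amino acid metabolism had median differences of 1.15 and 1.01, with SLC27A2 (Pjo24517) at 1117 and 1424, ARG1 (Pjo12892) at 426 and 391, and tdo2a (Pjo14354) and tdo2b (Pjo11656) at 389 and 336 in liver and 395 and 448 in the library labelled spleen. Against the highest of the other libraries, the medians of the 3 lists in liver were -0.22, -0.26 and -0.23. Fatty acid oxidation genes were at -0.30 in liver, a negative median at percentile 100, which turned to 1.74 after median-of-ratios scaling. Acadm, CPT1A, HADHB and Acaa2 (Pjo09481) were 202, 190.3, 124 and 104 in liver.

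Of the lists chosen for spleen, those of erythroid, T and NK cell, macrophage, thrombocyte and B cell genes were below the lower limit in the library labelled spleen, and those of spleen stroma and cell division passed neither limit. The erythroid list was -2.17 below the other libraries at percentile 0, and hba, hbb and alas2 were 521, 447 and 5.89 there against 1200, 1092 and 14.8 in liver. TFR2 (Pjo22527), an iron sensor of liver and red cell precursors, was 65.8 there and 59.1 in liver. The T and NK cell list was at -0.74 and percentile 0.95, and none of its 35 genes reached 1. Its highest members, Ccr9, Tcf7 (Pjo20665), eomes (Pjo18732) and CD28 (Pjo09865), were 0.99, 0.95, 0.85 and 0.62. The list of macrophages and antigen presentation was at -0.59 and percentile 0.19, with Cd74 (Pjo14686) at 60.5, CTSS (Pjo16299) at 19.9, slc40a1 (Pjo10292) at 11.8 and LGMN (Pjo13779) at 7.17. Cd74 was 2025 in gill. The thrombocyte list was at -1.56 and percentile 1.04, with THBS1 (Pjo16952), FLI1 (Pjo18520), Gp1bb and ITGB3 (Pjo12598) at 3.92, 3.19, 2.34 and 0.72. The B cell list was at -0.78 and percentile 0.54, with a CD22 copy (Pjo15975) at 6.15, BLNK at 1.41 and Swap70 (Pjo18162) at 1.11. It lay at percentile 6.16 after median-of-ratios scaling and at 23.24 with kidney left out of the reference. The spleen stroma list was at -1.01 and percentile 6.4, with CCL21 (Pjo12035), STAB2 (Pjo04520), Ccl19 (Pjo05937) and LTBR (Pjo12081) at 13.1, 3.97, 3.22 and 1.16. With kidney left out of the reference it lay at percentile 1.15. The cell division list was at -0.83 and percentile 97.35, and at 0.30 and percentile 98.62 after median-of-ratios scaling. With kidney left out of the reference it was at -0.43 and percentile 99.85. Its members ccnb1, Bub1b (Pjo20577), ube2c and rrm2 were 61.2, 38.2, 36.6 and 33.2.

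**Figure D4:**
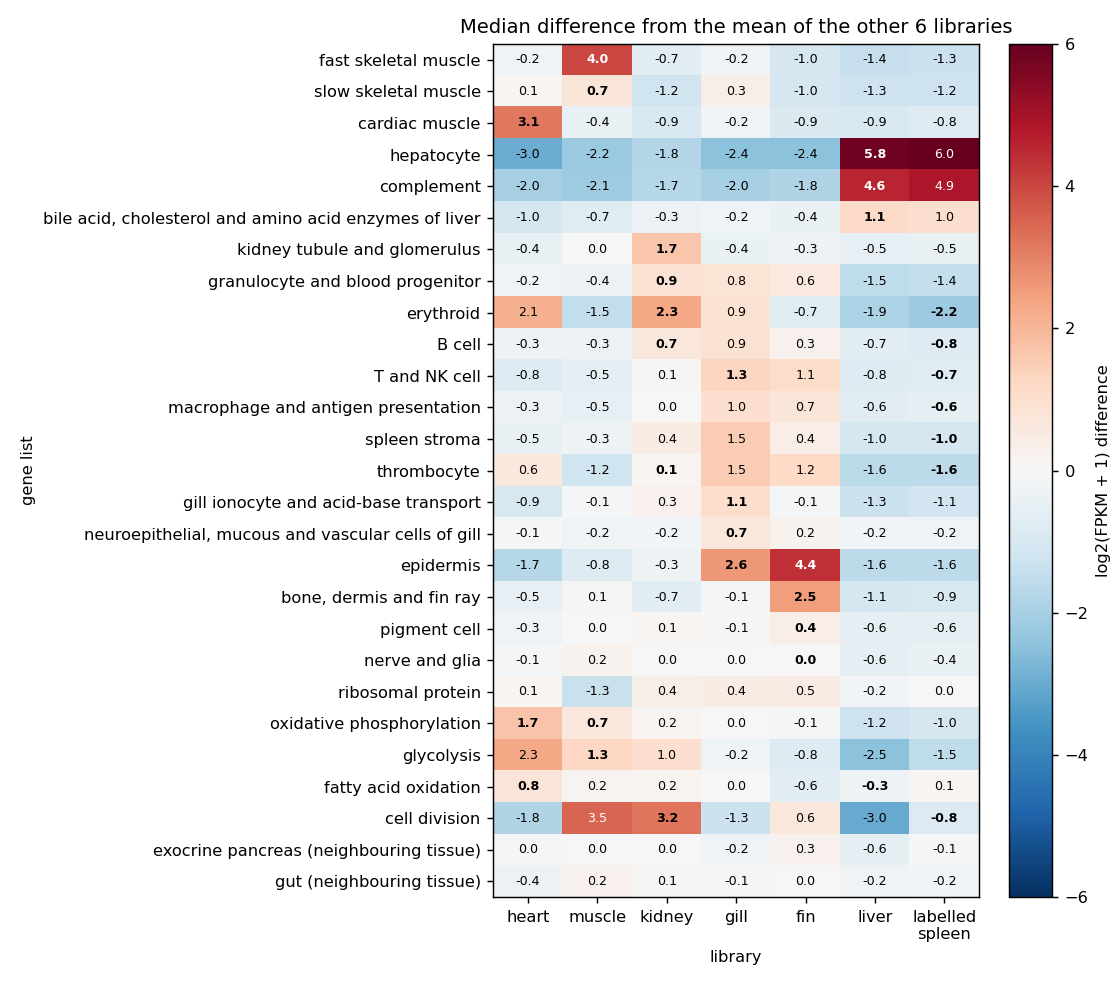
Each cell is the median over the genes of a gene list of log2(FPKM + 1) in a library (1 sample each) minus the mean of the other 6, for the 27 lists fixed before the data were examined. Bold values mark the libraries a list was chosen for, and hepatocyte genes stand at 5.82 in liver and 6.04 in the library labelled spleen.

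**Figure D5:**
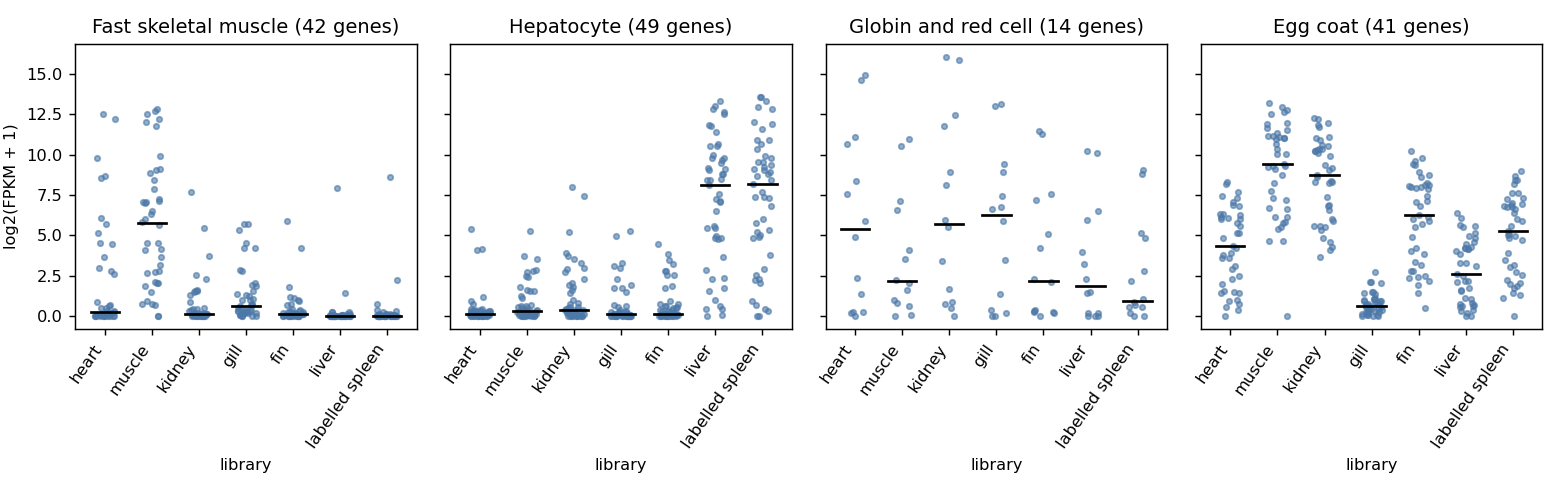
Points are genes of 4 lists and black lines their medians, as log2(FPKM + 1) in each library (1 sample each). The hepatocyte list is high in liver and in the library labelled spleen, with median FPKM of 279 and 291, and the egg coat list is high in muscle and kidney, at 676 and 429.

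In muscle against heart, 3198 genes were at least 5-fold higher in muscle and 967 in heart among genes with an FPKM of at least 10 in the higher of the pair. By its definition, the set of 1011 genes that followed the egg coat profile lies wholly on the muscle side. That set was chosen after the data were seen. Among named genes, the largest ratios on the muscle side belonged to TNNI2, acta1, MYLPF, TNNT3 and MYH1B, with log2 ratios of 12.07 for acta1, 11.88 for MYLPF and 11.66 for TNNT3. TNNI2 and MYH1B were listed at 0 in heart. On the heart side the largest ratios among named genes belonged to MYL4, MYH7, MYL7, nppa and TNNC1, with log2 ratios from -12.40 for MYH7 to -11.70 for TNNC1, and this MYL4 copy (Pjo05118) was listed at 0 in muscle. The copies of troponin C went opposite ways: TNNC1 (Pjo23378) was 4063 in heart and 0.22 in muscle, and Tnnc1 (Pjo23056) was 18.7 in heart and 221 in muscle. Other copies of MYL4 (Pjo01262) and ACTC1 (Pjo24801) were 1170 and 1108 in muscle and 0.82 and 0.82 in heart. The balance depended on the scaling. After median-of-ratios scaling 1730 genes were higher in muscle and 1650 in heart, and the share on the muscle side went from 76.8% to 51.2%.

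In the library labelled spleen against kidney, 556 genes were higher in the former and 4472 in kidney. The leading named genes of the former were the plasma protein genes apolipoprotein A-I, vtg1, FGB and tf and the fatty acid binding protein gene fabp10a, with log2 ratios from 14.75 to 12.95. Those of kidney were LYZ, fxyd2 (a regulator of ion transport) at 917, a cystatin-A-like gene (Pjo06104) at 349, Slc6a13 and TIMP3 at 1921, with log2 ratios of -10.12 for LYZ, -8.09 for Slc6a13 and -7.95 for TIMP3. fxyd2 and the cystatin-A-like gene were listed at 0 in the library labelled spleen. The direction of the balance turned with the scaling: median-of-ratios scaling gave 1318 genes higher in the library labelled spleen and 181 in kidney, and the share of the former went from 11.1% to 87.9%.

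In fin against gill, 629 genes were higher in fin and 552 in gill. KRT19, Prg4 and FGFBP2 led the named genes on the fin side at log2 ratios of 10.37, 9.72 and 9.18, followed by ZP3 and the ladderlectin-like gene at 8.10 and 8.08, which were 1168 and 1527 in fin and 3.27 and 4.64 in gill. On the gill side cnfn-b, TSTD1, rergl, the neural cell adhesion gene NCAM1 (Pjo15996) and rhcg1 led among named genes, from -9.71 for cnfn-b to -8.30 for rhcg1. NCAM1 was 796 in gill and 1.14 in fin. Without the 1011 genes that followed the egg coat profile across libraries, a set chosen after the data were seen, 403 genes were higher in fin and 550 in gill, so the larger side turned. It also turned with the scaling: after median-of-ratios scaling 438 genes were higher in fin and 482 in gill, and the share of fin went from 53.3% to 47.6%.

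Of the 21151 genes with an FPKM of at least 1 in some library, 2393 (11.3%) had a specificity index tau of at least 0.85 and 2833 (13.4%) one of at most 0.3. Tau runs from 0 for a gene at the same level in all libraries to 1 for a gene seen in a single one, and its median was 0.55. All 81 ribosomal protein genes reached 1 in every library, with list medians from 504 in muscle to 1508 in fin. RPL23 (Pjo03298), rps23 (Pjo12120) and RPS14 (Pjo20898) were 4546, 3934 and 3835 in fin. The ribosomal list was 0.49 higher in fin, at percentile 3.29, and at -0.43 and percentile 1.95 after median-of-ratios scaling. Its percentile in fin was 0.85 with kidney left out of the reference. In muscle it was at -1.34 and percentile 0, and in liver at -0.19, a negative median at percentile 100. Its median in the library labelled spleen was -0.00397, also at percentile 100. Lists of neighbouring tissues did not pass the limit in fin, where their median FPKM was highest. The exocrine pancreas list was at 0.26 and percentile 83.19, with CTRL (Pjo15596, a chymotrypsin-like protease) at 142, Cpa1 (Pjo24719) at 9.68, CELA2A (Pjo09161) at 4.77 and CPB1 (Pjo24116) at 4.22. In the library labelled spleen this list was at percentile 99.91 with a negative median of -0.11, and in heart at percentile 97.44 and -0.05. The gut list was at -0.04 and percentile 8.06, with fabp2 (Pjo00754), FABP6 (Pjo20955), ANPEP (Pjo08279) and VIL1 (Pjo10331) at 27.9, 14.4, 10.7 and 1.99. The count of genes at each end of tau depended on the scale: with a pseudocount of 0.1 it was 1140 and 7068.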

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

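Some alternatives were chosen after seeing the data. They left out genes on the egg coat profile, kidney and the library labelled spleen together, a library from the reference of a list, or the library labelled spleen from tau. The others, among them leaving out single tissues from the enriched counts, were chosen before. The log2 ratios of genes named for their enrichment or pairwise ratio kept direction and side of the limit in 222 of 222 alternatives. These genes were picked for the largest ratios, and some alternatives only loosen the rule, so this outcome was largely fixed by the choice. Gene lists stayed on the same side of the limits in 178 of 210 alternatives, where direction was compared only for lists beyond a limit. Of the counts of enriched genes, 73 of 96 stayed within 1.5 times. Each tissue had 1 sample, so no replicate could be left out and no paired analysis was possible. Depth is unknown, so absence cannot be read from a value listed at 0. No gene encoded by mitochondrial DNA was recognised by symbol, so only globins were left out. For the changes below the cause was not tested, except where fewer tissues or genes or a looser limit give a different count by construction.

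With an FPKM minimum of 5, detected genes numbered 6614 in heart, 3425 in liver, 10661 in kidney, 4690 in the library labelled spleen, 9755 in gill and 10435 in fin. With a minimum of 0.1 they numbered 15978 in liver and 17555 in the library labelled spleen. Without globins the 10 highest genes held 14.4% in heart, 11.7% in muscle, 36.5% in liver, 7.27% in kidney, 33.4% in the library labelled spleen, 9.88% in gill and 13.1% in fin.

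Correlations with a pseudocount of 0.1, with no filter, by Spearman and without egg coat profile genes were 0.943, 0.963, 0.925 and 0.972 for liver and the library labelled spleen, and 0.860, 0.907, 0.877 and 0.870 for muscle and kidney. In the same order they were 0.746, 0.831, 0.756 and 0.820 for gill and fin, and 0.614, 0.662, 0.606 and 0.640 for heart and muscle. They were 0.675, 0.690, 0.717 and 0.629 for kidney and the library labelled spleen, and 0.372, 0.529, 0.384 and 0.519 for muscle and gill.

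At 10-fold, enriched genes numbered 178 in heart, 1 in liver, 34 in kidney, 153 in gill and 123 in fin. In liver 4-fold, an FPKM minimum of 1 and rescaling to a common sum gave 4, 4 and 4. Median-of-ratios scaling gave 21 in liver, 32 in kidney, 13 in the library labelled spleen and 165 in fin. Muscle had 172 without heart, 1142 without kidney and 1152 without kidney and the library labelled spleen. Liver had 367 without the library labelled spleen, 5 without gill and 411 without kidney and the library labelled spleen. Kidney had 642 without muscle and 109 without gill, the library labelled spleen 385 without liver, gill 871 without fin and fin 782 without gill. Genes with tau of at least 0.85 numbered 5565 on the linear scale, 1140 with a pseudocount of 0.1 and 860 with a minimum of 10. Those with tau of at most 0.3 numbered 114 on the linear scale and 7068 with a pseudocount of 0.1.

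Against the highest of the other libraries, list medians were -0.55 for slow muscle, -0.22 for hepatocyte, -0.26 for complement and -0.23 for liver enzymes in liver, -0.17 for B cell and -0.36 for cell division in kidney, -0.82 for epidermis in gill, -0.0701 for nerve in fin and -0.34 for fatty acid oxidation in heart. They were 0.0487 for granulocyte in kidney, 0.00352 for ribosomal protein in fin, and -1.98 for B cell and -3.84 for cell division in the library labelled spleen. With 1 gene per root they were -0.11 for slow muscle, 2.36 for granulocyte, and -1.06 for B cell and -1.54 for stroma in the library labelled spleen. A pseudocount of 0.1 gave 2.22 for granulocyte, 1.53 for pigment cell, and -1.48 for B cell and -0.87 for cell division in the library labelled spleen. Median-of-ratios scaling gave 0.27 for granulocyte, -0.43 for ribosomal protein, 1.74 for fatty acid oxidation in liver, and -0.27 for B cell and 0.30 for cell division in the library labelled spleen. Without the library labelled spleen in the reference slow muscle was at 0.54. Without kidney it was at 0.59, ribosomal protein at 0.56, and B cell, stroma and cell division in the library labelled spleen at -0.53, -1.01 and -0.43.

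Median-of-ratios scaling gave 1730 genes higher in muscle and 1650 in heart, and 1318 in the library labelled spleen and 181 in kidney. Without egg coat profile genes 403 genes were higher in fin than in gill.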

Other observations

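The genes of this paragraph and the next were chosen after their values were seen. The tests on the library labelled spleen and on egg genes were chosen only after the results were seen, and the tests on the number of genes in liver were written before. The hormone gene epo (Pjo08123, erythropoietin) was 80.3 in heart, 4.65 in muscle and 4.57 in kidney, and the vessel growth factor vegfaa (Pjo04626) was 143 in heart and 19.1 in gill. In gill GCM2 (Pjo24054), a regulator of parathyroid development, was 60.1, and th (Pjo24446, tyrosine hydroxylase) 147. The immediate early genes fos (Pjo20470) and egr1 (Pjo14708) were 513 and 234 in gill, 371 and 198 in fin, 502 and 66.6 in heart and 41.6 and 8.34 in kidney. FOSB (Pjo18353) and junb (Pjo02736) were 241 and 731 in gill. The interferon-induced gene mx (Pjo24676) was 314 in fin and 53.2 in gill, and CXCL8 (Pjo00916) 94.0 and 88.6.

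In liver and the library labelled spleen the estrogen receptor gene esr1 (Pjo20086) was 22.4 and 13.9, igf2 (Pjo24444) 582 and 656, and cyp1a1 (Pjo17906) 3093 and 2807. Of 20 Hox genes of the tail, a list added after the data were seen, 15 were highest in fin, with a median difference of 1.40 at percentile 100. In muscle the list was at 0.40 and percentile 99.29, also above the limit, and in kidney at 0.34 and percentile 93.79. hoxa13a (Pjo19092) was 28.6 in fin and 0.65 in muscle, and hoxa13b (Pjo16674) was 29.6 in fin, 25.03 in heart and 15.9 in muscle. The pancreas enzyme genes CELA2A (Pjo09161) and CPB1 (Pjo24116) were 6.98 and 6.17 in heart, 5.35 and 5.55 in muscle and 6.64 and 6.24 in the library labelled spleen, and 0.03 and 0.03 in gill.

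Genes of 3 liver lists had a median ratio of 1.13 in the library labelled spleen over liver, over 78 genes with quartiles of 1.06 and 1.24. This value fits liver tissue in the tube labelled spleen, but it restates the pattern to be explained and gives no separate support. It is of FPKM as deposited, and the fit was not tested after scaling. Median-of-ratios scaling would lower it, since the log2 factors were -1.13 in the library labelled spleen and -1.89 in liver. The other limit set for liver tissue in that tube, at most 1.5 for blood, lymphoid and stroma genes, was also met. Against 1 library under both names stands the egg coat list, at a median ratio of 6.63. Blood, lymphoid and stroma genes had a median ratio of 0.945 over 37 genes, with quartiles of 0.446 and 1.14, which is under the 1.5 set for spleen RNA mixed with liver RNA and meets the value set against it, at most 1, but not by more than its spread. Erythroid genes were at 0.435, and B cell genes at 1.11 and macrophage genes at 1.12 showed no excess over the liver lists, so these values give no sign of spleen RNA, while a small share is not excluded. Liver tissue, which in fishes of this family can lie close to the spleen, may have been sampled, and the low erythroid and T and NK cell lists, at percentiles 0 and 0.95, argue against spleen cells as the source of the whole pattern.

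Egg coat genes in kidney, fin and the library labelled spleen were 0.588, 0.106 and 0.0507 times their level in muscle, and oocyte genes 0.759, 0.112 and 0.0555 times. In these 3 libraries the egg coat ratio differed by at most 1.29-fold from that of oocyte or cell division genes, which fits ovary RNA there. The ratios to muscle used 40 of 41 egg coat, 20 of 28 oocyte and 27 of 33 cell division genes. The others were under 10 in muscle and were left out, so the test could not show whether they followed. Outside this test, the ratios of egg coat, oocyte and cell division genes to muscle were 0.0267, 0.0221 and 0.0210 in heart and 0.00779, 0.00623 and 0.00783 in liver, and lay apart in gill at 0.00043, 0.00141 and 0.0217. Against reads leaking from the muscle library into kidney stands the median kidney to muscle ratio of fast muscle genes, 0.000573. Against reads leaking from the kidney library into the library labelled spleen stands the ratio of globin and red cell genes between them, 0.00907, where egg coat genes were at 0.0867. Leakage between other pairs of libraries was not tested. Ovary RNA may be present in muscle, kidney, fin and the library labelled spleen and, at lower shares, in heart and liver, and expression by the tissues themselves was not tested.

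Liver had 0.544 times as many genes with an FPKM of at least 1 as gill. Without the 100 highest genes of each library the ratio was 0.777, between what was set for and against a few genes taking most of the FPKM. After median-of-ratios scaling it was 0.9003, but this scaling brought every library to at least 0.9 of gill, so its outcome was fixed by centring. Both explanations and a tissue difference in the number of genes in use stay open, since depth is unknown.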
